A study of Mus musculus and Rattus norvegicus with 32 samples.

How the data were processed

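Liver RNA of male mice and male rats was measured on 32 Affymetrix arrays, 16 per species, in 8 groups of 4 given by the sample titles. Per the labels, animals received TCE or corn oil on 1 day or over 14 days and were 8 or 10 weeks old. Signals were made with MAS5, whose version is not given in the sources used here, per the submitters' processing notes. The deposited values were ratios: for every probe set without a missing value, the median of the 4 oil arrays of a species and schedule was 1 within 0.002. This was found from the values, and neither the division nor any scaling per array is described in the sources used here. The deposited tables therefore hold no signal level, and brightness over background could not limit or weight any value.

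Control probe sets (66 in mouse and 59 in rat) were left out of all tests, which left 12422 mouse and 8740 rat probe sets. The platform annotation gave 10833 mouse probe sets 1 gene symbol, 396 several and 1193 none, and 7006, 308 and 1426 in rat. Genes were named only from probe sets with 1 symbol, which covered 8251 mouse and 4736 rat genes, and 3055 symbols were shared. No pair of arrays in a group shared more than 0.00386 of its values, so none was treated as a duplicate.

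Log2 of the deposited ratio was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a mean per group over the 16 arrays of a species, and over all 32 arrays for the species comparison. Contrasts were TCE against oil per schedule, the difference of the 2 schedules' effects, and the mouse effect minus the rat effect. Adjusted p-values are Benjamini-Hochberg values over all probe sets or genes of a comparison, with a threshold of 0.05. Array control measures were compared with exact permutation tests.

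Several choices made before the data were examined could not be kept. A floor at the 20th percentile, a filter at the 40th percentile, a variance trend on signal, the brightest probe set per gene and the comparison of oil arrays between schedules all need signal levels. No floor, filter or pseudocount was used, the variance prior had no trend, and the probe set with the smallest within-group SD stood for a gene. The plan also called for quantile normalization where the 2% trimmed means of arrays differed by more than 5%, as they did (0.972 to 1.05 in mouse and 0.932 to 1.27 in rat). The deposited scaling was kept instead, a choice made after the data were examined. Quantile normalization gives oil and TCE ratios 1 common width, and the median within-group SD went from 0.384 to 0.558 on mouse oil arrays and from 0.398 to 0.303 on mouse TCE arrays. In rat it went from 0.425 to 0.587 and from 0.429 to 0.341. With it, 59, 7 and 0 probe sets passed in the mouse single-dose, repeated-dose and schedule comparisons, 2, 7 and 0 in rat, and 7 and 6 genes in the species comparisons.

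A set of 36 gene lists, fixed before the data were examined, was tested with limma's camera at a preset correlation of 0.01, in lists with at least 3 measured members; an estimated correlation was an alternative, under which no list passed in any comparison. Genes named in the text were, per TCE comparison, the 10 largest rises and 10 largest falls among genes past the threshold whose 4 TCE arrays all lay beyond all 4 oil arrays. For differences of effects they were the 5 largest each way, and in each list up to 4 members past the threshold, or up to 2 otherwise. Predicted genes without a proper name were skipped.

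The model was tested on simulated data with known changes of 0.5, 1 and 2 log2 units. In the mouse single-dose comparison (12420 probe sets) it recovered 2.99%, 32.8% and 71.2% of them, and in the mouse repeated-dose comparison 8.96%, 49.3% and 71.2%. In rat (8732 probe sets) it recovered 1.49%, 43.3% and 57.6% after 1 dose and 2.99%, 28.4% and 77.3% after repeated doses, and in the single-dose species comparison (3055 genes) 1.49%, 19.4% and 72.7%. False calls numbered 3 to 8 and no call had the wrong sign. The simulated noise was independent between probe sets, without 5' loss or shifts of whole arrays. These counts therefore do not measure false calls on the real arrays, where other splits of 8 arrays called up to 267 probe sets in mouse and 131 in rat.

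Alternatives were quantile normalization, centring on array medians, log2(ratio + 1), only the groups of a comparison, array weights, a replicate block, the mean of a gene's probe sets, and leaving out each array in turn. Added after the data were examined were a variance trend on the mean log2 ratio, leaving out the noisiest 40% of probe sets, the Gapdh control's 3' minus 5' log2 ratio as a covariate, and leaving out arrays where that value was above 1. The last leaves 1 TCE array in each mouse schedule, 3 in rat after 1 dose and 2 in rat after repeated doses, and limma then takes the spread of a lone array from the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.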

Results

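Liver transcripts were measured on Affymetrix arrays in male mice of the B6C3F1 hybrid strain and in male Sprague-Dawley type (SD) rats that received trichloroethylene (TCE), a chlorinated solvent that the liver metabolises, or the corn oil used to deliver it. Per the labels, the dose was 1500 mg per kg body weight by gavage, given once or daily over 14 days, and livers were taken 18 h after the last dose. The 32 arrays formed 8 groups of 4, 1 for each combination of species, schedule and treatment, and the series set out to compare the species. Mouse arrays gave 12422 probe sets and rat arrays 8740 once control probe sets were left out. Each deposited value was a ratio to the median of the 4 oil arrays of the same species and schedule, so the tables hold no signal level and the number of arrays limits the precision. Counts of changed probe sets depended strongly on array scaling: the plan made before the data were examined called for quantile normalization, and the deposited scaling was kept instead after they were examined, so both counts are given for each comparison. The median within-group SD of a probe set was 0.42 on the log2 scale in mouse and 0.46 in rat. The labels give 4 samples per group without stating that each came from its own animal, so p-values measure the spread between these samples.

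Control probe sets that track RNA quality differed between arrays. The Gapdh control signal at the 3' end relative to the 5' end, which grows when transcripts are shortened, exceeded a log2 value of 1 on 10 arrays, of which 9 were TCE arrays. These 10 are the arrays of 5' loss below, set by Gapdh alone. Both ends are ratios to the oil median of the same species and schedule, so the value shows loss relative to those oil arrays. A loss shared by the oil arrays of a schedule could not show. Their beta-actin value was only -0.12 on rat repeated-dose TCE 4, 0.28 on mouse repeated-dose oil 1 and 0.48 on mouse repeated-dose TCE 3. On the others it was 0.77 to 1.90. Mean values were 1.51 ± 0.95 (SD, n = 4) on mouse single-dose TCE arrays and -0.03 ± 0.17 (SD, n = 4) on their oil arrays, a difference of 1.54 (exact permutation test, two-sided, p = 0.0571). Mouse repeated-dose arrays differed by 0.78 (exact p = 0.371), rat single-dose arrays by 0.30 (exact p = 0.886) and rat repeated-dose arrays by 1.08 (exact p = 0.0571). The smallest p that 4 against 4 arrays allow is 0.0286. The beta-actin 3' to 5' value differed between TCE and oil by 0.76 (exact p = 0.0286) and 0.72 (exact p = 0.0571) in mouse after 1 dose and repeated doses. In rat it differed by 0.06 (exact p = 0.857) and 0.70 (exact p = 0.229). In mouse, the spiked hybridization controls were lower on TCE arrays by -0.62 after 1 dose and -1.15 after repeated doses (exact p = 0.0286 each).

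**Figure D1:**
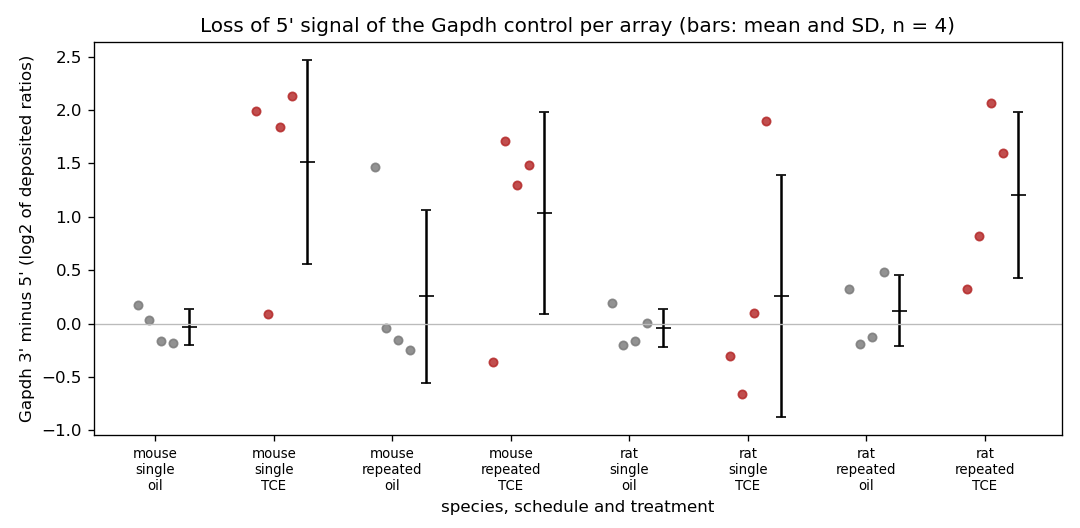
Log2 of the Gapdh control's 3' ratio minus that of its 5' ratio (vertical axis) for each of 32 arrays by species, schedule and treatment (horizontal axis), with oil arrays in grey, TCE arrays in red and bars for the mean and SD of 4 arrays. The mouse single-dose TCE arrays lie between 0.09 and 2.13, and 1 mouse repeated-dose oil array lies at 1.46.

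After 1 dose, mouse liver showed higher transcripts of fatty acid omega-oxidation and peroxisomal oxidation, and of the proteasome, and lower transcripts of coagulation and complement factors. Cyp4a14, a microsomal fatty acid omega-hydroxylase, rose by 4.46 ± 0.58 (log2 change ± SE, n = 4 and 4, limma adjusted p = 0.000682, 0.0252 with quantile normalization and 0.978 with a variance trend on the mean log2 ratio). The deposited division fixes the oil medians, so that mean follows the TCE change itself and the trend is no independent test. Acot1, a cytosolic acyl-CoA thioesterase, rose by 2.38 ± 0.23 (adjusted p = 6.67e-05), and Aldh3a2, a fatty aldehyde dehydrogenase, by 1.58 ± 0.15. Of 5 omega-oxidation and thioesterase genes 4 rose and 1 fell, with a median change of 2.19 (camera adjusted p = 0.000259; adjusted p = 0.0795 with an estimated correlation). Of 15 peroxisomal fatty acid oxidation genes 7 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.00189; adjusted p = 0.0795 with an estimated correlation). Among them Ehhadh, the peroxisomal bifunctional enzyme, rose by 2.02 ± 0.17, Pex11a, a factor of peroxisome division, by 1.63 ± 0.19 and the thiolase Acaa1b by 1.0 ± 0.16. The Gapdh 3' to 5' value was higher on 3 of the 4 TCE arrays behind these groups, and with it as a covariate the peroxisomal median was 0.51 and the omega-oxidation median 1.49.

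Proteasome subunits and heat shock proteins were higher as lists in the same comparison. Of 30 proteasome subunits 10 rose and none fell at adjusted p under 0.05 over all probe sets (12 and 0 adjusted over the list alone), with a median change of 0.48 (camera adjusted p = 1.50e-08; adjusted p = 0.0795 with an estimated correlation). Psma7 rose by 1.11 ± 0.19, Psma5 by 1.01 ± 0.15 and Psmc3 by 0.97 ± 0.20. Of 13 heat shock proteins 5 rose and 0 fell, led by the chaperone Hsp90aa1 at 1.99 ± 0.26 (camera adjusted p = 0.00189; adjusted p = 0.114 with an estimated correlation). Among 21 NRF2 target genes, which respond to electrophiles and oxidants, 4 rose and 0 fell (6 and 0 adjusted over the list alone), including Gstm3 by 0.92 ± 0.20 and Gsr by 0.85 ± 0.19; the camera adjusted p was 0.0212, 0.319 with 5' loss as a covariate, and the adjusted p = 0.145 with an estimated correlation. Lipid uptake and storage genes had 4 of 16 members higher, among them Apoa4 by 2.06 ± 0.30 and Vnn1 by 1.12 ± 0.20 (camera adjusted p = 0.0447; adjusted p = 0.114 with an estimated correlation), and the call was lost after centring (adjusted p = 0.0593), with the mean of a gene's probe sets (adjusted p = 0.232) and with 5' loss as a covariate (adjusted p = 0.083). The median went from 0.09 to -0.22 with that covariate.

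In mouse after 1 dose 9 of 36 lists were lower, with complement and coagulation genes holding the most members that fell. Of 23 complement and coagulation genes 12 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 1.50e-08; adjusted p = 0.0795 with an estimated correlation). F2, which encodes prothrombin, fell by 1.07 ± 0.21, Proc, an anticoagulant protease, by 0.98 ± 0.19 and C8g by 0.90 ± 0.14. Of 22 acute phase proteins 4 fell, including Saa4 by 3.57 ± 0.66 (-1.88 with 5' loss as a covariate, adjusted p = 0.06) and the fibrinogen chain Fgb by 0.92 ± 0.18 (camera adjusted p = 0.0263; adjusted p = 0.391 with an estimated correlation). Of 16 cholesterol synthesis genes 4 fell, led by Fdps, with a change of -1.61 ± 0.37 (camera adjusted p = 0.0166, 0.0729 with 5' loss as a covariate; adjusted p = 0.527 with an estimated correlation). Cyp2f2, a periportal cytochrome P450, fell by 1.27 ± 0.16, 1 of 2 lower among 11 periportal genes (camera adjusted p = 0.0143; adjusted p = 0.0795 with an estimated correlation). Of 11 male-predominant genes 4 fell, among them Egfr by 0.82 ± 0.15 and Igf1 by 0.57 ± 0.13 (camera adjusted p = 0.00917; adjusted p = 0.114 with an estimated correlation). Amino acid catabolism had 2 of 18 genes lower, among them Gnmt, which uses the methyl donor SAM, by 1.38 ± 0.27 (camera adjusted p = 0.0143; adjusted p = 0.267 with an estimated correlation). Slc1a2 fell by 0.92 ± 0.15, alone among 12 pericentral genes (camera adjusted p = 0.0447; adjusted p = 0.268 with an estimated correlation), a call lost after centring (adjusted p = 0.0593) and quantile normalization (adjusted p = 0.0659). Gluconeogenesis had 0 of 8 genes passing (camera adjusted p = 0.042, 0.0627 with 5' loss as a covariate; adjusted p = 0.114 with an estimated correlation), and stellate cell and matrix genes had 1 of 18 lower, Sparc at -1.09 ± 0.23 (camera adjusted p = 0.042, 0.083 with 5' loss as a covariate; adjusted p = 0.268 with an estimated correlation). With 5' loss as a covariate, 10 of the 15 lists called in this comparison were still called. Without TCE 3, the acute phase, cholesterol, gluconeogenesis, lipid uptake, pericentral and stellate lists each lost their call, as they did without 1 or more other arrays, with adjusted p up to 0.209.

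The largest single-gene changes in this comparison included further transcripts. Psat1, a serine synthesis enzyme, rose by 3.89 ± 0.62 (adjusted p = 0.00275), Sprr1a, a small proline-rich protein, by 3.36 ± 0.48 and Ptprb, an endothelial phosphatase, by 2.61 ± 0.42. Habp2, a plasma protease, fell by 3.49 ± 0.55 (adjusted p = 0.00272) and Dnase1l3, a secreted nuclease, by 2.50 ± 0.28. In total 517 probe sets were higher and 514 lower at limma adjusted p under 0.05, 1031 together. With 3 of the 4 TCE arrays showing 5' loss, 278 probe sets passed with it as a covariate. Without those 3 arrays 18 passed, from 1 TCE array that was assumed to vary like the other groups. Leaving out 1 array gave 519 without TCE 1, 653 without TCE 3, 611 without TCE 4, 596 without oil 2 and 555 without oil 3. Of the 20 genes with the largest changes, 10 kept their call whichever array was left out; the adjusted p of the others, among them St6galnac6 and Tgfb1, reached at most 0.136. Of 42 further list members past the threshold 27 kept it likewise, and the others, among them Fdps without TCE 3, reached an adjusted p of at most 0.122. Quantile normalization left 59 calls and 14 of the 62 named genes past the threshold: Acot1, Aldh3a2, Apoa4, Cyp2f2, Cyp4a14, Dnase1l3, Ehhadh, Gna14, Habp2, Hsp90aa1, Mgll, Pex11a, Psat1 and Sprr1a. Centring on array medians, which removed a shift of -0.09 in the median of all probe sets, gave 721 higher and 355 lower (67.0% higher against 50.1%).

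After repeated doses, mouse liver again showed higher omega-oxidation and peroxisomal genes, together with lower complement, acute phase, endoplasmic reticulum (ER) and interferon genes. Cyp4a14 rose by 5.22 ± 0.58 (adjusted p = 0.000406, and 0.965 with the variance trend, under the same limit), Acot1 by 2.18 ± 0.23 and Ehhadh by 2.35 ± 0.17 (adjusted p = 1.53e-05). Cyp4a10, whose probe set can also bind related transcripts, rose by 2.97 ± 0.60. Of 5 omega-oxidation and thioesterase genes 4 rose (camera adjusted p = 1.74e-06; adjusted p = 0.0521 with an estimated correlation). Of 15 peroxisomal genes 6 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.000222; adjusted p = 0.0521 with an estimated correlation). Of 17 mitochondrial fatty acid oxidation genes 2 rose and 1 fell, among them Cpt2, which returns acyl groups to CoA inside mitochondria, by 0.83 ± 0.15 (camera adjusted p = 0.00639; adjusted p = 0.21 with an estimated correlation).

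Of 23 complement and coagulation genes 15 fell (19 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 1.38e-07; adjusted p = 0.0521 with an estimated correlation). Hc, which encodes complement C5, fell by 1.37 ± 0.21, F2 by 1.18 ± 0.21 and C9 by 1.0 ± 0.20. Of 22 acute phase proteins 9 fell and 1 rose, among them Itih4 by 1.55 ± 0.21 and Fgb by 1.40 ± 0.18 (camera adjusted p = 0.0019; adjusted p = 0.193 with an estimated correlation). Among 16 ER stress genes 10 fell and 1 rose (camera adjusted p = 0.00115; adjusted p = 0.0879 with an estimated correlation), including the chaperone Hspa5 by 1.41 ± 0.22 and the disulfide isomerase Pdia3 by 1.94 ± 0.24, while Asns, an asparagine synthesis enzyme, rose by 1.0 ± 0.24 (adjusted p = 0.0194, and 0.0591 without TCE 2). Of 23 interferon response genes 7 fell (11 adjusted over the list alone; camera adjusted p = 0.0019; adjusted p = 0.148 with an estimated correlation). In that list Ifit1, an interferon-induced RNA-binding protein, fell by 2.81 ± 0.44 and Usp18 by 2.13 ± 0.32. Member counts of the complement, acute phase, ER stress and interferon lists are on the deposited scaling. Over all probe sets, the number lower went from 1053 to 506 after centring. No named member of these lists kept its call with quantile normalization, while their camera calls at the preset correlation held under it and after centring. Of 12 bile acid genes 4 fell (8 adjusted over the list alone), led by Cyp7a1, the rate-limiting enzyme of bile acid synthesis, with -1.85 ± 0.39 (camera adjusted p = 0.00638; adjusted p = 0.221 with an estimated correlation). Of 11 male-predominant genes 5 fell, among them Egfr by 1.47 ± 0.15 (camera adjusted p = 0.00348; adjusted p = 0.117 with an estimated correlation). Periportal genes had 2 of 11 lower, Ctsc by 1.28 ± 0.22 and Cyp2f2 by 0.92 ± 0.16 (camera adjusted p = 0.0061; adjusted p = 0.0544 with an estimated correlation). Amino acid catabolism had 5 of 18 lower, including Oat by 1.22 ± 0.27 (camera adjusted p = 0.00382, 0.0556 with the mean of a gene's probe sets; adjusted p = 0.19 with an estimated correlation).

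In the same comparison 4 further lists passed. Fatty acid synthesis had 1 of 13 genes higher, Elovl6 at 1.05 ± 0.28, and 1 lower, Pklr at -1.21 ± 0.29 (camera adjusted p = 0.00809; adjusted p = 0.342 with an estimated correlation). Gluconeogenesis genes had 0 of 8 passing and 4 lower when adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.117 with an estimated correlation). Among 13 immediate early genes 4 fell and 1 rose, with the transcription factor Jun lower by -2.47 ± 0.46 (camera adjusted p = 0.0489, 0.0635 with 5' loss as a covariate and 0.0594 with the mean of a gene's probe sets; adjusted p = 0.156 with an estimated correlation). Macrophage markers had 2 of 17 lower, C1qa at -0.99 ± 0.29 and Csf1r at -0.63 ± 0.15 (camera adjusted p = 0.0433, 0.126 with 5' loss as a covariate, 0.173 with the mean of a gene's probe sets and 0.0585 with quantile normalization; adjusted p = 0.342 with an estimated correlation). Each of these 4 lists lost its call without oil 3 and without 1 or more other arrays, with adjusted p up to 0.181.

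Among the largest changes, S100g, a calcium-binding protein, rose by 3.64 ± 0.52 (1 of its 2 probe sets passing, both higher) and Grin2b, a glutamate receptor subunit, by 2.21 ± 0.29. Cmah, which makes N-glycolylneuraminic acid, fell by 3.19 ± 0.71, Vti1a, a vesicle SNARE protein, by 3.11 ± 0.48 and Efna4, an ephrin ligand, by 2.86 ± 0.32. Altogether 278 probe sets were higher and 1053 lower. The Gapdh value exceeded 1 on TCE arrays 2, 3 and 4 and on oil array 1, and 58 probe sets passed without these arrays, from 1 TCE array against 3 oil arrays, the lone array being assumed to vary like the other groups. Centring, which removed a median shift of -0.15, gave 475 higher and 506 lower (48.4% higher against 20.9%), and a fit on these 8 arrays alone 388 calls. Quantile normalization left 7 calls and 6 of the 64 named genes past the threshold, Acot1, Ahnak, Aldh3a2, Cyp4a14, Ehhadh and Tbc1d10a. Of the 2 Tbc1d10a probe sets, only that used here was higher on the deposited scaling. Without oil 2 the count was 687, without oil 4 772 and without TCE 2 692. Of the 20 genes with the largest changes 18 kept their call whichever array was left out, Arhgap29 and Nasp being the others. Of 44 further list members past the threshold 27 kept it likewise, and 17, among them Elovl6, Pklr, C1qa and Csf1r, lost it without TCE 2, with adjusted p up to 0.132 over the arrays left out.

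**Figure D2:**
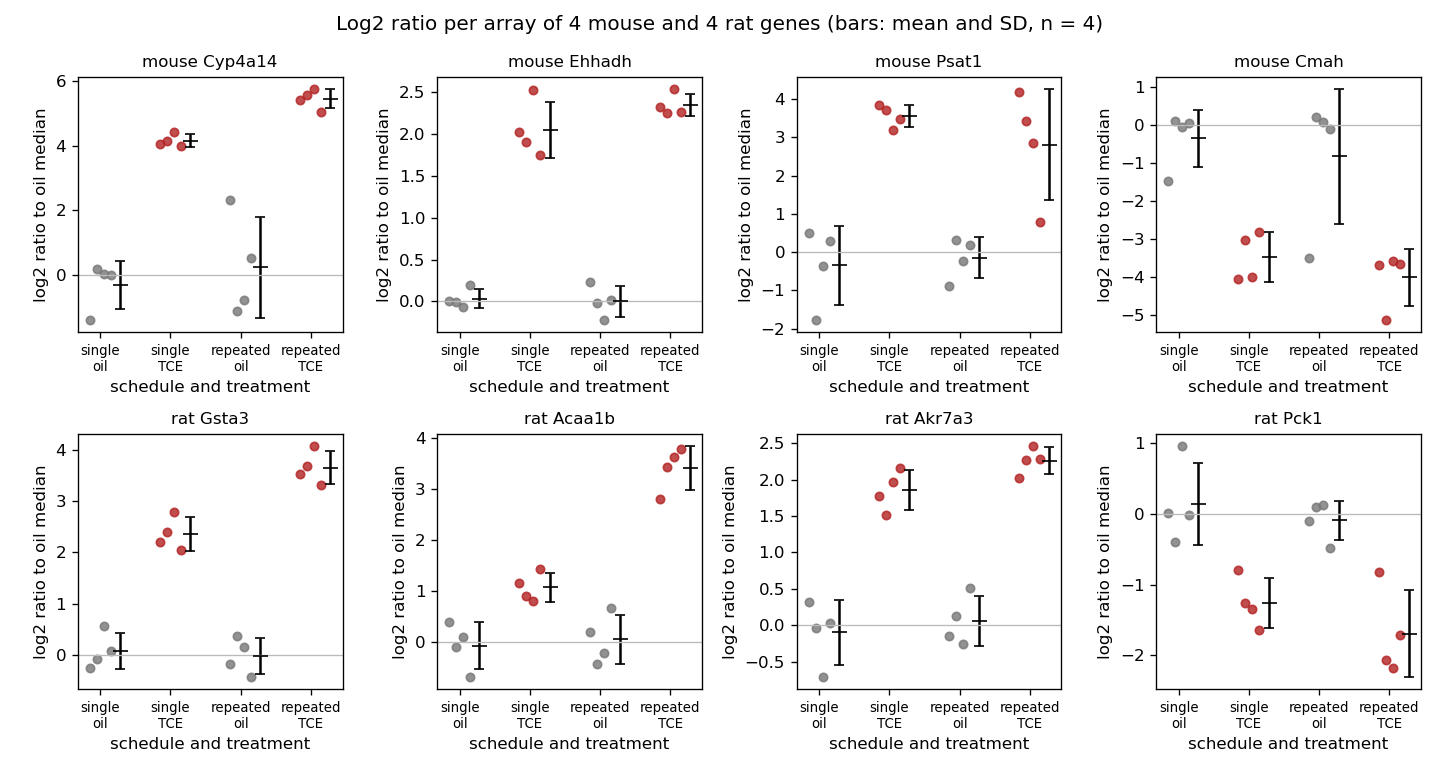
Log2 ratio to the median of the oil arrays (vertical axis) of 4 mouse genes (upper panels) and 4 rat genes (lower panels) on each array by schedule and treatment (horizontal axis), with oil arrays in grey, TCE arrays in red and bars for the mean and SD of 4 arrays. Mean mouse Cyp4a14 was 4.15 after 1 dose and 5.45 after repeated doses of TCE, and mean rat Gsta3 was 2.36 and 3.66.

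The schedules were then compared within mouse through the difference of their TCE effects. Mt1, a metal-binding metallothionein, rose by 1.71 ± 0.30 after 1 dose and fell by 1.98 ± 0.30 after repeated doses, a difference of -3.68 ± 0.43 (adjusted p = 0.00318, n = 4 per group, kept whichever array was left out). Crnkl1, a splicing factor, moved the same way, with effects of 2.07 and -1.19 and a difference of -3.26 ± 0.31 (adjusted p = 0.000497). The difference for Fas, a death receptor, was -3.21 ± 0.54 (adjusted p = 0.0198). Hsp90aa1 had a difference of -1.87 ± 0.36 (adjusted p = 0.042) and Hspa5 of -1.52 ± 0.31 (adjusted p = 0.0427), and both were lost without single-dose TCE 1 among others. Of 36 lists 4 passed, a number that 33 of 100 draws of the treatment labels reached. Proteasome subunits, with a median difference of -0.57 (camera adjusted p = 0.00016; adjusted p = 0.535 with an estimated correlation), had 0 of 30 members passing over all probe sets and 1 higher and 9 lower adjusted over the list alone. Heat shock proteins (median -0.70, camera adjusted p = 0.00185) and ER stress genes (median -0.54, camera adjusted p = 0.0307, 0.0525 with quantile normalization, up to 0.0635 without single-dose TCE 2, repeated-dose oil 3 or TCE 2) had 1 member lower each, and neither held with estimation (adjusted p = 0.535 with an estimated correlation for each). Fatty acid synthesis had a median of 0.41 (camera adjusted p = 0.00185; adjusted p = 0.542 with an estimated correlation) with no member passing, Thrsp standing at 1.91 ± 0.68 (adjusted p = 0.146). In all, 26 probe sets had a higher and 83 a lower effect after repeated doses, and quantile normalization gave 0 by limma, with 2338 at an unadjusted p under 0.05 on the deposited scaling. Leaving out any of 11 of the 16 arrays moved the count by over 1.5 times, to as few as 21 without single-dose TCE 1, and 0 passed without arrays of 5' loss, which leaves 1 TCE array per schedule. Centring gave 30 higher and 48 lower (38.5% higher against 23.9%).

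In rat liver after 1 dose, NRF2 target genes were higher as a list and 7 other lists were lower. Gsta3, a glutathione S-transferase, rose by 2.29 ± 0.25 (adjusted p = 0.000952) on a probe set of a design that related transcripts can share, with all 3 of its probe sets passing, and Akr7a3, an aldehyde reductase, by 1.95 ± 0.24 (adjusted p = 0.00243). They led the NRF2 target genes, of which 3 of 17 rose (8 and 1 lower adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.00842; adjusted p = 0.322 with an estimated correlation). Aldh1a1, a retinaldehyde dehydrogenase, rose by 1.55 ± 0.28, and Gclm, a subunit of glutathione synthesis, by 1.37 ± 0.33 (adjusted p = 0.0499). Among falling genes were Slc37a4, a glucose-6-phosphate transporter, by 1.02 ± 0.17, Aph1a, a gamma-secretase subunit, by 1.09 ± 0.17, and Pck1, a gluconeogenic enzyme, by 1.40 ± 0.33 (adjusted p = 0.0481).

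Of 36 lists 7 were lower in rat after 1 dose. Amino acid catabolism had 0 of 22 genes passing and 5 lower adjusted over the list alone, with Gnmt at -0.92 ± 0.24 (camera adjusted p = 0.000404; adjusted p = 0.0627 with an estimated correlation). Cholesterol synthesis had 0 of 15 passing, with Ebp at -0.88 ± 0.21 (camera adjusted p = 0.000419; adjusted p = 0.449 with an estimated correlation). Among 8 genes of TCE metabolism 1 fell, Gstt2, with -1.01 ± 0.20 (camera adjusted p = 0.00157; adjusted p = 0.139 with an estimated correlation). Periportal genes had 1 of 12 lower, Pck1 (camera adjusted p = 0.00422; adjusted p = 0.0627 with an estimated correlation), and complement genes 1 of 14, F10, at -0.93 ± 0.18 (camera adjusted p = 0.00833; adjusted p = 0.0627 with an estimated correlation). Macrophage markers had 0 of 7 passing, with Cd14 at -1.05 ± 0.28 (camera adjusted p = 0.00842; adjusted p = 0.449 with an estimated correlation). Exocrine pancreas markers had 0 of 11 passing, with a median of -0.91 (camera adjusted p = 0.0144, 0.0672 after centring; adjusted p = 0.69 with an estimated correlation), and the median was 0.37 without oil 3, whose mean over these markers was 5.11 log2 units, while the adjusted p was 0.211 without TCE 3. Other groupings of the 8 arrays called up to 12 lists.

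**Figure D3:**
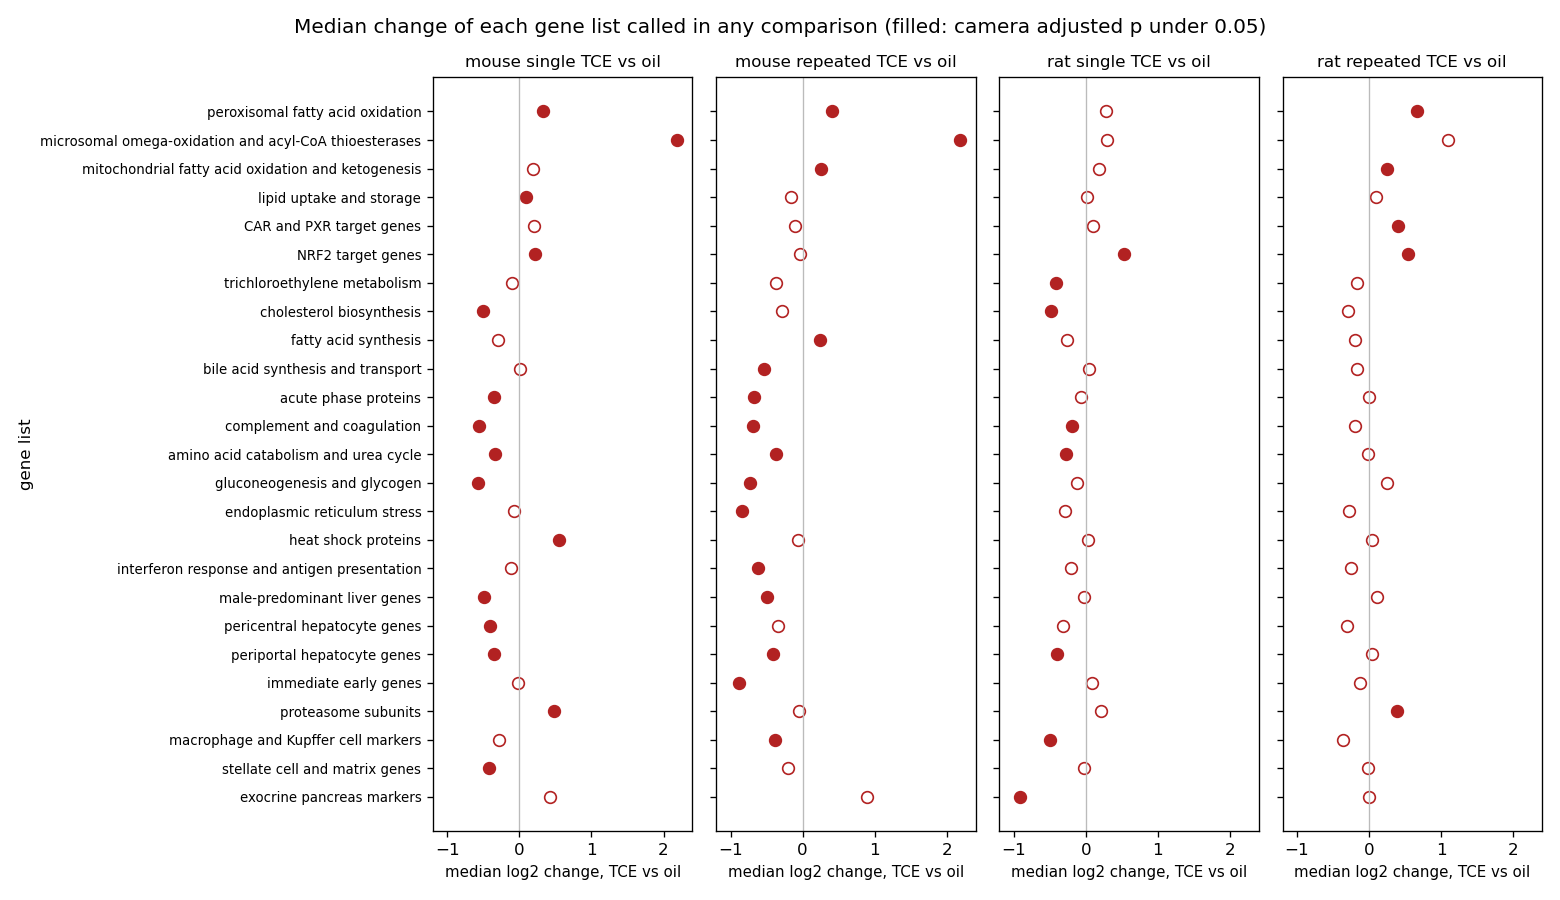
Median log2 change between TCE and oil (horizontal axes) of every gene list that passed in at least 1 of 4 comparisons (vertical axis), with filled points for a camera adjusted p under 0.05 at the preset correlation. Median changes of the omega-oxidation list were 2.19 and 2.18 in mouse and 0.30 and 1.10 in rat after 1 dose and repeated doses.

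Over all rat probe sets, 106 were higher and 44 lower after 1 dose. Of the 20 genes with the largest changes 4 kept their call whichever array was left out, Gsta3, Akr7a3, Aph1a and Slc37a4, and the adjusted p of the others reached at most 0.147. Thoc2 at 4.12 ± 0.88, Epha3 at 3.05 ± 0.52 and Hspa13 at 2.98 ± 0.52 had the 3 largest rises among those 16. The further list members Gclm, Gstt2 and F10 lost their call without TCE 1, among other arrays, with adjusted p up to 0.148. Without TCE 1 the count was 22, without TCE 2 55, without TCE 4, the array with 5' loss, 25, without oil 2 38 and without oil 4 31. Array weights gave 395, the fit on these 8 arrays alone 69, and quantile normalization 2. Gsta3 alone kept its call there, of the 23 named genes past the threshold. Centring, which removed a median shift of 0.14, gave 77 higher and 107 lower (41.8% higher against 70.7%).

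After repeated doses, rat liver showed higher peroxisomal and mitochondrial fatty acid oxidation genes and NRF2 target genes. Acaa1b, a peroxisomal thiolase, rose by 3.37 ± 0.30 (adjusted p = 3.48e-05), Pex11a by 1.88 ± 0.20 and Ech1, an enoyl-CoA isomerase, by 1.75 ± 0.29. Of 12 peroxisomal genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 4.94e-05; adjusted p = 0.091 with an estimated correlation). Of 19 mitochondrial oxidation genes 4 rose (8 adjusted over the list alone), including Eci1, an enoyl-CoA isomerase, by 1.66 ± 0.21 and Cpt2 by 1.28 ± 0.21 (camera adjusted p = 0.00544, 0.0949 with the mean of a gene's probe sets; adjusted p = 0.091 with an estimated correlation). Of 17 NRF2 target genes 4 rose (8 and 1 lower adjusted over the list alone), led by Gsta3 at 3.68 ± 0.25 (adjusted p = 2.65e-06) and Akr7a3 at 2.20 ± 0.24 (camera adjusted p = 0.000122; adjusted p = 0.091 with an estimated correlation). Proteasome subunits had 4 of 21 higher, among them Psmd1 by 1.23 ± 0.21 and Psma2 by 0.96 ± 0.18 (camera adjusted p = 0.00266, 0.106 with 5' loss as a covariate and 0.0949 with the mean of a gene's probe sets; adjusted p = 0.74 with an estimated correlation). Of 35 splits of these 8 arrays 3, the real one included, had a proteasome median as far from 0 (0.38, highest other -0.44), so chance was not excluded. Among 15 CAR and PXR target genes, regulated by xenobiotic receptors, Aldh1a1 rose by 2.78 ± 0.28 (camera adjusted p = 0.0454, 0.585 with 5' loss as a covariate, up to 0.138 without oil 1, 2 or 3 or TCE 2 or 3; adjusted p = 0.601 with an estimated correlation). The Gapdh 3' to 5' value exceeded 1 on TCE arrays 3 and 4 behind these groups, and without both the median of peroxisomal genes was 0.74 and of NRF2 targets 0.54. Other groupings of these arrays called up to 6 lists against 5.

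Me1, which makes NADPH from malate, rose by 2.77 ± 0.34 (adjusted p = 0.000685), with 4 of its 5 probe sets passing. Cirbp, a cold-inducible RNA-binding protein, fell by 1.85 ± 0.27, Cdk5, a cyclin-dependent kinase, by 2.62 ± 0.44, and Pck1 by 1.61 ± 0.33 (adjusted p = 0.0185, and up to 0.0623 without oil 1 or TCE 2). Fam111a had the largest rise, 5.73 ± 1.0 (adjusted p = 0.0085). In total 189 probe sets were higher and 57 lower. Of the 20 genes with the largest changes 12 kept their call whichever array was left out, as did 7 of 14 further list members. The other 7 were lost without oil 1, with adjusted p up to 0.106 over the arrays left out. Without oil 1 the count was 100, without oil 4 147, without TCE 2 120 and without TCE 4 154. With 5' loss as a covariate it was 72, without the arrays of 5' loss 133, with array weights 430 and with these 8 arrays alone 106. After quantile normalization it was 7, and Acaa1b, Aldh1a1 and Gsta3 kept their call of the 34 named genes past the threshold.

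Between rat schedules no probe set differed (limma, 0 of 8740 on the deposited scaling and 0 after quantile normalization, with 818 at an unadjusted p under 0.05). Of 36 lists 3 had higher effects after repeated doses. None of the 3 passed with the mean of a gene's probe sets (adjusted p of 0.0579, 0.0977 and 0.0579 in the order below). Peroxisomal fatty acid oxidation had a median difference of 0.33, with Acaa1b at 2.22 ± 0.42 (adjusted p = 0.221) and 4 members higher adjusted over the list alone (camera adjusted p = 0.00596; adjusted p = 0.332 with an estimated correlation). Without single-dose oil 3 that list had an adjusted p of 0.0578. Mitochondrial oxidation genes had a median of 0.39, with 3 members higher adjusted over the list alone (camera adjusted p = 0.00596; adjusted p = 0.185 with an estimated correlation), and amino acid catabolism 0.31 with none (camera adjusted p = 0.00596; adjusted p = 0.332 with an estimated correlation). In 62 of 100 draws of the treatment labels, as many lists passed, the real grouping included.

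The species were compared on 3055 genes with the same symbol, as the mouse effect minus the rat effect. The array types differ, and probe sets of different arrays can have different response ranges. A difference of effects is therefore not separated from a difference of probe sets. Rat symbols came from the platform annotation without a check by gene ID, and the rat Gsta3 probe set can bind related transcripts. After 1 dose Psat1 differed by 4.04 ± 0.67 (adjusted p = 0.000644), Sprr1a by 3.09 ± 0.50 and Apoa4, an intestinal and hepatic apolipoprotein, by 2.71 ± 0.44, each with a higher effect in mouse. Gsta3 differed by -2.73 ± 0.34 (adjusted p = 4.62e-05), Syt6, a synaptotagmin, by -2.77 ± 0.61 and Epha3, an ephrin receptor, by -3.36 ± 0.77, each with a higher effect in rat. In total 46 genes had a higher and 83 a lower effect in mouse, 0 of 33 lists differed by limma's camera test, and 645 genes had an unadjusted p under 0.05. Without mouse TCE 1 the count was 82 and without rat oil 2 81. Centring, which removed a median difference of -0.19, gave 110 higher and 37 lower (74.8% higher against 35.7%), and quantile normalization left 7. Of the 10 genes with the largest differences it left Apoa4, Gsta3, Psat1 and Sprr1a. Of these 10 8 kept their call whichever array was left out, Lrrc8a and Prm2 being the others.

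After repeated doses, the species difference was again large for Gsta3, at -4.11 ± 0.34 (adjusted p = 7.63e-09), and for Psat1 at 2.80 ± 0.67 and S100g at 2.89 ± 0.62. Plg, which encodes plasminogen, differed by 2.76 ± 0.67 (1.28 with 5' loss as a covariate, adjusted p = 0.0208) and Msx1, a homeobox factor, by 3.82 ± 0.69. Fam111a, by -6.33 ± 1.13, and Onecut1, a hepatic transcription factor, by -4.42 ± 1.02, had higher effects in rat. Acute phase proteins differed as a list, with a median of -0.60, 0 genes higher and 6 lower of 18 (1 and 9 adjusted over the list alone), among them Fga by -1.39 ± 0.20 and Itih4 by -1.54 ± 0.26. The camera adjusted p was 0.0269, 0.0633 after centring, 0.189 with quantile normalization, 0.086 with the mean of a gene's probe sets, up to 0.0833 when mouse TCE 1, mouse oil 2 or rat oil 2 was left out, and the adjusted p = 0.666 with an estimated correlation. In 50 of 100 draws of the treatment labels at least 1 list passed. In total 61 genes had a higher and 260 a lower effect in mouse, against 88 and 135 after centring (39.5% higher against 19.0%), which removed a median difference of -0.23, and 6 after quantile normalization. There Gsta3, Msx1 and Plg kept their call of the 14 named genes past the threshold.

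Across genes, TCE effects after 1 dose and repeated doses correlated in mouse (8250 genes, Pearson r = 0.267, Spearman rho = 0.237) and in rat (4736 genes, r = 0.355, rho = 0.313). Permutation of the treatment labels gave p = 0.0099 for each r, the smallest that 100 draws can give, and genes are not independent replicates. Between species the correlation was 0.134 after 1 dose (rho = 0.144, permutation p = 0.0594) and 0.0701 after repeated doses (rho = 0.0465, permutation p = 0.139). Over these 4 relations the adjusted p was 0.0198 for the within-species pairs, 0.0792 after 1 dose and 0.139 after repeated doses. Repeated-dose oil 1, the mouse oil array with 5' loss, correlated at 0.221 with single-dose TCE arrays of 5' loss, against 0.204 to 0.228 for repeated-dose TCE arrays of 5' loss and 0.0835 for TCE 1 without it. Part of the mouse correlation was therefore not separated from RNA quality. With 5' loss as a covariate r was 0.313 (permutation p = 0.0099). Both schedules share 1 fitted slope there, which can itself raise r, so this value does not settle the question. In mouse the permutation p was up to 0.0693 without single-dose oil 2 or 4 or repeated-dose oil 2, 3 or 4 (r down to 0.211), and 0.307 without arrays of 5' loss (r = 0.123), which leaves 1 TCE array per schedule. In rat it was 0.0594 without single-dose oil 3 or TCE 4 (r of 0.301 and 0.279) and without the noisiest 40% of probe sets (r = 0.435). Between species after 1 dose it was 0.0099 with the planned quantile normalization (r = 0.131) and under 0.05 when any of 13 of the 16 arrays was left out, but 0.693 with 5' loss as a covariate (r = 0.0313). In mouse, 44 probe sets rose under both schedules and 200 fell under both, against 11.6 and 43.6 for independent lists, and 10 moved in opposite directions. In rat 50 rose and 11 fell under both, against 2.29 and 0.287. Between species, calls were counted over the 3055 shared genes, a call set that differs from the counts per species above. After 1 dose 145 genes rose in mouse and 127 in rat, and 210 and 95 fell. Of these, 19 rose and 22 fell in both, against 6.03 and 6.53. After repeated doses 91 and 202 rose and 347 and 87 fell, with 14 rising and 14 falling in both, against 6.02 and 9.88.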

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

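The tests of 5' loss, of the excess of falls, and of 5' loss and scaling behind the proteasome rise were chosen after the results were seen; the regroupings of arrays and the spiked-control tests were set before.

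The number of probe sets called between TCE and oil stood next to 5' loss and lower spiked controls on TCE arrays. Other splits of the 8 arrays argued against chance: 1 of 35 splits, the real one, called as many in mouse after 1 dose (1031, highest other 9) and repeated doses (1331, highest other 267), and in rat (150, highest other 3; 246, highest other 131). With the Gapdh 3' to 5' value as a covariate, called probe sets kept a median share of 0.779 of their change in mouse after 1 dose (quartiles 0.603 and 0.969, 205 still called). The share was 0.988 (1083 still called) after repeated doses, and 1.01 (148) and 0.944 (65) in rat. These probe sets were called on the same arrays that set the covariate's slope, which can favour a high share. Other splits that held the arrays of 5' loss together called at most 9 (4 splits) in mouse after 1 dose and 1 (14 splits) in rat after repeated doses. Rat after 1 dose had only 1 such array. In mouse after repeated doses the 1 such split called 267, while no other false split called more than 2. The split counts argue against 5' loss as the whole cause, rat after 1 dose aside, and leave a partial role open. With the spiked controls as a covariate the median share was 1.17 (SE 1.31 times as large, 672 of 1031 still called) after 1 dose in mouse, which argues against a hybridization difference as the whole cause, within the limit that oil and TCE arrays did not overlap in these controls under either schedule. After repeated doses it was 0.946 (quartiles 0.625 and 1.24) and met the bound written beforehand for ruling the explanation out, but that bound was wrong in leaving out precision, since the SE grew 1.93 times and 5 of 1331 probe sets were still called; it was set aside only after that result was seen, and a hybridization difference and TCE cannot be told apart there.

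In mouse after repeated doses, 1053 of 1331 called probe sets were lower. After centring on array medians 51.6% of calls were falls (46.6% to 55.1% with 1 array left out). Centring pulls rises and falls towards balance whatever the cause, so it cannot tell the scaling of arrays from a wider fall of transcripts under TCE, and both stay open. With 5' loss as a covariate the share was 80.0% (76.5% to 83.4%), which argues against 5' loss as the source of the excess.

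Proteasome subunits were higher in mouse after 1 dose, with a median of 0.48 over 30 members. The median was 0.643 with 5' loss as a covariate (quartiles 0.31 and 0.922), which argues against 5' loss as the whole cause. After centring it was 0.57 (quartiles 0.273 and 0.906). Centring removed a shift of -0.09 in the median of all probe sets, so it could only raise this value and cannot test scaling. Of 35 splits 1, the real grouping, had a median as far from 0 (highest other 0.361). That is the smallest share 35 splits allow. The list was singled out by its result on these same arrays, so chance was not excluded. The repeated minus single difference of -0.57 was matched by 2 of 100 draws of the labels (highest other 0.574). These draws model no TCE effect under either schedule, so they cannot test whether the 2 effects were equal. A response of the proteasome to a first dose is a hypothesis that may be followed up, found and tested on the same arrays. It is limited by an adjusted p of 0.0795 with an estimated correlation, and differences in hybridization were not tested for this list.

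For counts of lists and of differing effects, regrouping gave the following values. In mouse only the real split of 35 called as many lists after 1 dose (15, highest other 12) and after repeated doses (15, highest other 12). That is the smallest share 35 splits allow, and other splits came close. It argues against chance for these counts without excluding it. Nor was chance excluded in rat, where 9 of 35 splits gave as many lists after 1 dose (8, highest other 12) and 2 of 35 after repeated doses (5, highest other 6). Among differences of effects, 33 of 100 draws gave as many lists between mouse schedules (4, highest other 13), 62 of 100 between rat schedules (3, highest other 9) and 50 of 100 between species after repeated doses (1, highest other 8), so chance was not excluded. Only the real grouping reached the count of probe sets differing between mouse schedules (1 of 100 draws, 109 called, highest other 81). The same held for genes differing between species after 1 dose (1 of 100, 129 called, highest other 69) and repeated doses (1 of 100, 321 called, highest other 154). Shuffled labels model no TCE effect rather than equal effects, so these draws cannot exclude chance for a difference of effects. Between rat schedules all 100 of 100 draws gave at least the 0 called by limma (highest other 6; 818 at an unadjusted p under 0.05).

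Single arrays stood apart from the other 3 of their group by Dixon's criterion in 21 of 278 groups tested, where chance gives about 1 in 20, or 13.9. Among array measures these were rat single-dose TCE 4 in the median log2 ratio (0.0552) and in the beta-actin 3' to 5' value (0.99), and in the Gapdh 3' to 5' value mouse single-dose TCE 2 (0.0935) and mouse repeated-dose oil 1 (1.46). In mouse after 1 dose they were oil 1 in Cyp4a14 (-1.42) and Cmah (-1.47), oil 2 in Pfn2 (-2.77) and Gpat4 (-0.31), and TCE 2 in St6galnac6 (-1.46). In mouse after repeated doses they were oil 2 in S100g (1.89), oil 1 in Trpc4 (-0.97) and Cmah (-3.48), and TCE 2 in Cmah (-5.14). In rat they were single-dose oil 4 in Mpv17l (0.92), single-dose TCE 3 in Acads (-0.49), repeated-dose oil 2 in Pparg (1.08) and repeated-dose TCE 4 in Cirbp (-1.04). Among list means they were male-predominant genes on mouse single-dose TCE 2 (-0.61), gluconeogenesis on mouse repeated-dose oil 3 (0.15), exocrine pancreas markers on rat single-dose oil 3 (5.11) and NRF2 targets on rat repeated-dose TCE 3 (0.57).

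The effect of TCE differed between mouse schedules, repeated minus single, for Ccr1l1 (3.09), Rag1 (2.50), Grin2b (2.46), Sft2d1 (2.18), Prss30 (2.00), Ccdc47 (-4.67), Xrn1 (-4.65), Mt1 (-3.68), Crnkl1 (-3.26) and Fas (-3.21). The first 5 and Ccdc47 and Xrn1 lost the call without single-dose TCE 1, with adjusted p up to 0.105. Of the 2 Rag1 probe sets, only that given here had a higher effect after repeated doses. Between species after 1 dose, mouse minus rat, it differed for Psat1 (4.04), Sprr1a (3.09), Tgfb1 (2.89), Apoa4 (2.71), Lrrc8a (2.35), Epha3 (-3.36), Prm2 (-3.05), Akap12 (-2.95), Syt6 (-2.77) and Gsta3 (-2.73). After repeated doses it differed for Msx1 (3.82), Rhoa (2.95), S100g (2.89), Psat1 (2.80), Plg (2.76), Fam111a (-6.33), Onecut1 (-4.42), Acsm2 (-4.13), Gsta3 (-4.11) and Prps2 (-3.59). With 5' loss as a covariate Tgfb1 was 1.30 after 1 dose (adjusted p = 0.155) and, after repeated doses, Rhoa was 1.32 (adjusted p = 0.252) and Plg 1.28 (adjusted p = 0.0208). Rhoa also lost its call in 12 of 16 fits with 1 array left out (adjusted p up to 0.0774). As lists, median differences between mouse schedules were 0.41 for fatty acid synthesis, -0.54 for ER stress, -0.70 for heat shock proteins and -0.57 for the proteasome. Between rat schedules they were 0.33 for peroxisomal oxidation, 0.39 for mitochondrial oxidation and 0.31 for amino acid catabolism, and between species -0.60 for acute phase proteins after repeated doses.

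Control probe sets outside the tested tables differed between mouse TCE and oil arrays: the beta-actin 3' to 5' value by 0.76 after 1 dose, and the spiked hybridization controls by -0.62 after 1 dose and -1.15 after repeated doses (exact p = 0.0286 each).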

How the results depend on the processing

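The covariate for 5' loss, leaving out arrays of 5' loss, the variance trend and leaving out the noisiest 40% of probe sets were chosen after the data were seen. The mean log2 ratio behind the trend follows the TCE change itself, because the oil medians are fixed by the deposited division. In the order mouse single, mouse repeated, mouse schedule difference, rat single, rat repeated, rat schedule difference, and species difference after 1 dose and repeated doses, the main counts were 1031, 1331, 109, 150, 246, 0, 129 and 321. Quantile normalization, planned before the data were examined and replaced after, gave 59, 7, 0, 2, 7, 0, 7 and 6; the wider oil groups it makes are 1 part of this by construction. Without arrays of 5' loss the counts were 18, 58, 0, 29, 133, 1, 36 and 160; this leaves 1 TCE array in each mouse schedule, assumed to vary like the other groups, so the mouse and species counts do not show dependence on 5' loss itself. Counts that moved by over 1.5 times with 5' loss as a covariate were 278 in mouse single, 183 in the mouse schedule difference, 256 in rat single and 72 in rat repeated. Those with only the groups compared were 388 in mouse repeated, 69 in rat single and 106 in rat repeated, with fewer arrays to estimate the spread. Array weights gave 219 in the mouse schedule difference, 395 and 430 in rat and 263 between species after 1 dose. With log2(ratio + 1) they were 306 in the mouse schedule difference, 234 and 392 in rat and 6 in the rat schedule difference. Without the noisiest 40% they were 672 in the mouse schedule difference, 441, 526 and 5 in rat and 207 between species after 1 dose, and with a variance trend 28 in rat single. Where construction does not show it, the cause was not tested.

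Leaving out 1 array gave 519 to 1187 in mouse single, 687 to 1271 in mouse repeated, 21 to 118 in the mouse schedule difference, 22 to 128 in rat single, 100 to 316 in rat repeated, 0 to 1 in the rat schedule difference, and 81 to 181 and 254 to 361 between species. Leaving the rat schedule difference aside, where most arrays tie at 0, the lowest counts were without TCE 1, oil 2, single-dose TCE 1, TCE 1, oil 1, rat oil 2 and mouse TCE 2.

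Lists called numbered 15, 15, 4, 8, 5, 3, 0 and 1, and 0 in each comparison with an estimated correlation. With the mean of a gene's probe sets they were 14, 12, 6, 8, 3, 0, 0 and 0. Of the 51 list calls, 4 were lost with quantile normalization, 4 with centring, 10 with that mean, 9 with 5' loss as a covariate, 9 without its arrays, 5 with the replicate block and 10 of 50 without the noisiest 40%. For the species difference after 1 dose, 5' loss as a covariate or leaving out its arrays gave 1; after repeated doses, centring gave 0, and leaving out the noisiest 40% or arrays of 5' loss 2. Leaving out 1 array gave 9 to 15 and 11 to 15 in mouse, 3 to 6 in its schedule difference, 8 to 10 and 4 to 6 in rat, 3 to 4 in its schedule difference, and 0 to 2 for each species difference. The exocrine pancreas list in rat single turned from -0.91 to 0.37 without oil 3 (-1.37 without oil 2, the lowest), and the lipid uptake median in mouse single from 0.09 to -0.22 with 5' loss as a covariate and -0.19 without its arrays. Across genes, the correlation of mouse schedules was 0.123 without arrays of 5' loss (permutation p = 0.307, 1 TCE array per schedule) and 0.211 to 0.317 with 1 array left out, losing its call in 5 of 16 cases. For rat schedules it was 0.435 without the noisiest 40% (permutation p = 0.0594) and 0.276 to 0.407, losing its call in 2 of 16. Between species after 1 dose the call, missed on the deposited scaling (permutation p = 0.0594), was gained with quantile normalization (0.131, permutation p = 0.0099), without the noisiest 40% (0.243, permutation p = 0.0198) and in 13 of 16 cases with 1 array left out (0.104 to 0.15). With 5' loss as a covariate it was 0.0313 (permutation p = 0.693) and without arrays of 5' loss 0.0695 (permutation p = 0.396), and the correlation after repeated doses was 0.0441 to 0.1.

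Of 219 named gene results past the threshold, 188 lost their call with quantile normalization, 171 without arrays of 5' loss, 67 with 5' loss as a covariate, 42 with the trend, 21 with centring, 18 with log2(ratio + 1) and 2 with array weights, and 75 of 183 with only the groups compared, all in the same direction. With 1 array left out, 482 of 2040 lost it.

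Deviations of same-numbered oil and TCE arrays correlated between 0.0512 and 0.0766 in mouse single and -0.174 and -0.0016 in mouse repeated. In rat they correlated between -0.119 and 0.0693 after 1 dose and -0.0408 and 0.0778 after repeated doses, with 0 pairs above 0.1. Differently numbered arrays gave -0.0896 to 0.0539, -0.0624 to 0.098, -0.0663 to 0.18 and -0.224 to 0.176 in the same order. Same-numbered pairs thus lay at the top of the range in mouse single, where a weak pairing is not excluded, but not in the other groups. With the replicate number as a block, counts were 190, 264, 0, 8, 42, 1, 55 and 180, the list between species after repeated doses went to 0, and 128 of the 219 named gene results lost their call. The dim probe filters, the floor and the oil comparison between schedules were not run, because ratios hold no signal level.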

Other observations

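Lipid handling genes outside the changes already described differed in direction between members. In rat after repeated doses Cd36, a fatty acid transporter, rose by 2.76 ± 0.54 (SE, n = 4 and 4, limma adjusted p = 0.0145), Mgll, a monoacylglycerol lipase, by 1.97 ± 0.22 (adjusted p = 0.000414), and Apoa4 fell by 1.52 ± 0.32 (adjusted p = 0.02). Of 6 rat omega-oxidation genes, Cyp4a1 and Aldh3a2 rose by 1.29 ± 0.28 and 1.02 ± 0.20 and Cyp4a8 fell by 1.06 ± 0.26, while the list had a camera adjusted p of 0.0528. In mouse, Cyp2b10, a cytochrome P450 regulated by CAR, rose by 1.31 ± 0.21 and 1.08 ± 0.21 after 1 dose and repeated doses. Vnn1, a pantetheinase, rose by 2.14 ± 0.20 in mouse after repeated doses. Glul, which encodes glutamine synthetase, rose by 0.89 ± 0.17 in mouse after repeated doses and fell by 1.21 ± 0.24 and 1.54 ± 0.24 in rat after 1 dose and repeated doses. In rat after 1 dose all 4 Glul probe sets were lower and 1 passed (limma adjusted p = 0.028), a call lost without some arrays. Mt2, chosen after its values were seen, rose by 2.17 ± 0.35 in mouse after 1 dose (adjusted p = 0.00288), stood at -0.19 after repeated doses (adjusted p = 0.772) and had a schedule difference of -2.36 (adjusted p = 0.0456), as a second metallothionein beside Mt1.

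A further 11 lists passed in no comparison. Of 33 cell cycle genes in mouse, 0 passed by limma in either schedule (medians -0.03 and -0.03), and in rat Tyms rose by 1.34 ± 0.32 after 1 dose, 1 of 19. Among p53 targets, Mdm2 rose in rat by 0.97 ± 0.20 and 0.85 ± 0.20, and Fas fell in mouse after repeated doses by 2.04 ± 0.38. Circadian genes in mouse after 1 dose included Rora at -1.21 ± 0.30, Nr1d1 at -0.89 ± 0.20 and Cry1 at 0.77 ± 0.21. Endothelial markers went both ways, with Tek at -1.03 ± 0.26 in mouse after repeated doses and Pecam1 at -1.43 ± 0.26 and Lyve1 at 1.14 ± 0.22 in rat after repeated doses. Alas2, of the red blood cell list, fell by 1.30 ± 0.20 and 0.98 ± 0.20 in mouse. Lymphocyte markers had a median of -0.47 in rat after repeated doses (camera adjusted p = 0.0528), and Ptprc, a leukocyte phosphatase, fell by 1.99 ± 0.52 in mouse after repeated doses. Neutrophil, cholangiocyte, adipose and muscle, female-predominant and aryl hydrocarbon receptor lists had camera adjusted p of 0.726, 0.882, 0.509, 0.665 and 0.388 in mouse after 1 dose, and 0.593, 0.162, 0.245, 0.245 and 0.748 after repeated doses. In rat the values were 0.636, 0.842, 0.616, 0.302 and 0.0918 after 1 dose, and 0.63, 0.975, 0.588, 0.93 and 0.333 after repeated doses.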
